A study of Cupriavidus metallidurans CH34 with 7 samples.

How the data were processed

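The 7 arrays of 1 slide, scanned once, measured total RNA of Cupriavidus metallidurans CH34 on a custom single-colour (Cy3) Agilent design. Cells were grown in mineral salts medium with gluconate, exposed to the metal compound and spun down, and RNA was purified on columns with DNase treatment, per the labels' protocols. Groups came from the sample titles, with 3 cisplatin, 3 Pt(IV) chloride and 1 Au-NP sample.

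The deposited scanner tables hold the intensity of each spot on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the file headers. Its processed signal is the intensity after background subtraction and detrending within the array, per the file headers, with no scaling between arrays. The authors also deposited a value table of 9735 rows, each under a probe ID, an intensity on a linear scale whose columns share a mean of 1.03 and have medians from 0.187 to 0.211. It correlated with the scanner values of the same array at 0.993 to 0.995 across genes on the log2 scale, and less with those of any other array. Its background treatment, scaling and averaging of probes stay unknown, and 5 of its values on Pt(IV) chloride replicate 3 were not above 0. Checked on 2 cases, a row of that table matched the mean signal of several features that share the start of a name. The row of Rmet_R0051 gave a log2 difference of 1.60 between cisplatin and Pt(IV) chloride, where the mean of Rmet_R0051 and Rmet_R00510 gave 1.57 and Rmet_R0051 alone 2.07. The row of dnaE21 gave a log2 difference of 1.00 for the Au-NP array, where the mean of 7 dnaE and dnaE2 features gave 1.00 and dnaE21 alone 2.78.

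From these files, log2 of the processed signal minus the array's 75th percentile was computed for 15207 probes, leaving out control spots and the 1 to 6 spots per array flagged as outliers. The 75th percentile signal was between 360 (Au-NP) and 492 (Pt(IV) chloride replicate 2). A probe entered when it was well above background on at least 3 of the 6 platinum arrays, which 14207 probes were, and a gene was the mean of its entering probes. Of genes with 2 entering probes, these differed by over 1 log2 unit in 3 of 2983 for the platinum difference and in 30 of 3000 for the Au-NP difference. The probes carry 10100 names in the files, of which 3419 are intergenic, 329 are gene symbols (some with an added digit for further features of a gene) and the rest locus tags. No table pairing tags with names was used here, so features with a tag are named by it and at most 2 in each direction are printed per comparison.

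Cisplatin and Pt(IV) chloride were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg over 6477 gene features, threshold 0.05), without covariates. The fit was tested on simulated data for this comparison with 6470 features, where it recovered 92 of 100 genes changed by 1 log2 unit and 96 of 100 changed by 2, with 14 other features called. The simulated noise was normal and independent between features and arrays, with variances drawn from the fit's own prior. These figures therefore check the fit under its own assumptions and do not give its power on the real arrays. All arrays came from 1 slide and 1 scan, so no slide block could be fitted. Replicate numbers in the titles were shared by the platinum groups. Deviations from the group means correlated at 0.586, 0.555 and 0.212 between arrays numbered 1, 2 and 3, and at no more than 0.116 between arrays of different number, so by the rule of a correlation over 0.1 in every pair the numbers were taken to pair the samples, and the fit with a replicate block is given where it changes a call.

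Before the data were examined, 30 gene lists were set from textbook knowledge, by gene symbol or, for 5 lists of metal resistance, metal uptake and iron acquisition, by locus tag. The content of the tag lists rests on general knowledge of the strain and could not be checked in the files. Of the 30 lists 16 had a measured member, and the 12 with at least 5 were tested with limma camera (preset correlation 0.01), with an estimated correlation and with fry beside it, adjusted over the lists. Counts within a list are also given adjusted over the list alone. A further 9 lists were added after seeing the data and serve the closing section only.

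The Au-NP array was described by its difference from the mean of the 2 platinum group means and by whether it lay outside the range of all 6 platinum arrays by at least 1 log2 unit, over 6505 gene features well above background on that array or on 3 platinum arrays. A list median is given as a percentile among 10000 random lists of the same size matched on mean level in 10 bins. The random lists were drawn feature by feature, so the percentile makes no allowance for members that move together, as neighbouring genes may. Where all probes of a gene were not well above background on one side, its fold is a bound, computed against the higher of its own value and the lowest signal among probes well above background, and written "at least".

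The rule for named genes was also set before the data were examined. For the platinum comparison it takes genes with an adjusted p under 0.05 and groups that do not overlap, up to 12 per direction, and where fewer than 5 pass also the 10 with the smallest p. From each list it takes up to 4 members by size of difference. Of 15 fixed genes only recA and groEL have a feature under that name. For the Au-NP array it takes the 12 highest and 12 lowest features outside the range and up to 4 per list. Other members of the DNA damage and flagellar lists, and genes in the closing section, were named after their values were seen. Of the 10 smallest p, the 7 beyond the calls were locus tags and are not printed, and their adjusted p was between 0.0744 and 0.392.

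Alternatives were normexp background correction (offset 50), quantile normalization, median centring, the authors' value table, other filters on dim probes, the brightest probe, keeping outlier-flagged spots, a trended and robust spread, array weights, the replicate block, other thresholds, other reference arrays and leaving out each array. Alternatives added after seeing the data were both arrays numbered 1 left out, intergenic features in the same fit, the DNA damage list without dnaE2 features and, for the Au-NP array, outlier-flagged spots kept.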

Results

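The series asked how Cupriavidus metallidurans CH34, a soil bacterium known for its resistance to many heavy metals, responds at the level of its transcripts to different platinum compounds. Total RNA of the wild type was hybridised to 7 single-colour arrays, 1 per sample. Cisplatin, a platinum(II) complex with ammine and chloride ligands, was given at 50 µM for 10 min in 3 samples. Pt(IV) chloride, a platinum salt of a higher oxidation state, was given at the same dose and for the same time in 3 samples. A gold preparation labelled Au-NP was given at 320 µM for 60 min in 1 sample. Untreated samples were not analysed here, so each direction below is between treatments and not against resting cells. Between 90.7% and 94.5% of the 15207 probes were well above background on each array, no spot was saturated, and the number of arrays limits the precision. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

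The first comparison set cisplatin against Pt(IV) chloride at matched dose and time. The transcript profiles of cells exposed to these compounds lay close together, and 3 of 6477 gene features differed. Rmet_R0051 was 4.20-fold higher with cisplatin. Its normalised log2 level was 4.68 ± 0.06 (SD, n = 3) with cisplatin and 2.61 ± 0.11 (SD, n = 3) with Pt(IV) chloride. The difference was 2.07 on the log2 scale (95% interval 1.86 to 2.28), with a limma adjusted p of 3.03e-04. A further feature, Rmet_R00510, was 2.05-fold higher with cisplatin (log2 difference 1.04, 95% interval 0.79 to 1.29, limma adjusted p = 0.04996). The files do not say how these features relate, but the authors' value table has a single row for them. Rmet_5144 was 2.34-fold higher with Pt(IV) chloride, with levels of -3.66 ± 0.11 (SD, n = 3) for cisplatin and -2.44 ± 0.22 (SD, n = 3) for Pt(IV) chloride (limma adjusted p = 0.04996), and its log2 difference of -1.23 became -0.59 with normexp. For these 3 features the files give a locus tag and pair it with no gene name. Rmet_R0051 and Rmet_R00510 belong to 68 features whose tag carries an R, and what kind of transcript these are was not looked up. Over these 68 the median log2 difference was 0.01, 35 were higher with cisplatin, and the next largest difference was 0.60 in size. Each of the 3 differing features was separated in all 6 arrays, as were 19.2% of features, where chance gives 10%.

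**Figure D1:**
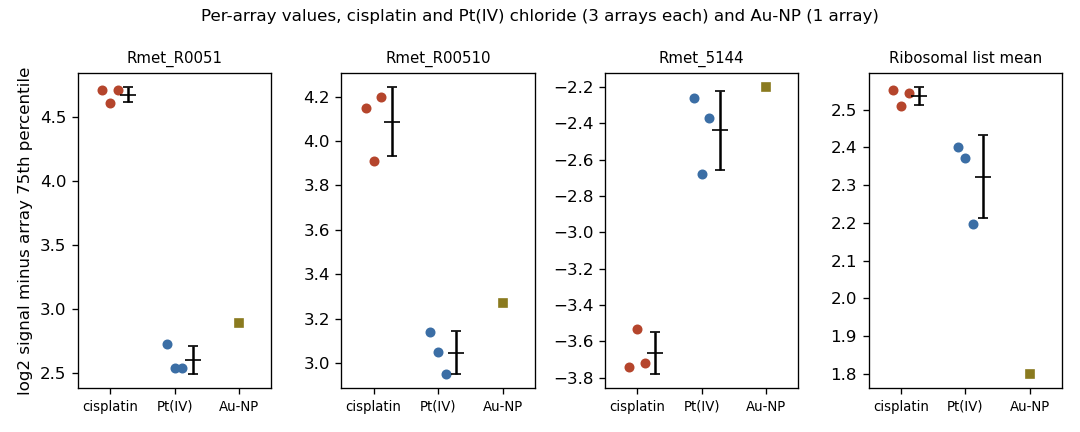
Normalised log2 signal (vertical axis, log2 signal minus the array's 75th percentile) of the 3 features that differed and of the mean of 47 ribosomal protein genes. Points are single arrays of cisplatin and Pt(IV) chloride with the group mean and SD beside them (n = 3), and squares are the 1 Au-NP array. The Pt(IV) chloride arrays of Rmet_R0051 lie between 2.54 and 2.73 and the cisplatin arrays between 4.61 and 4.71.

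Only Rmet_R0051 kept its call with the replicate number as a block, where the count was 1 and both other features had a limma adjusted p of 0.172. It was also the 1 feature called when any of 5 of the 6 arrays was left out. Without Pt(IV) chloride replicate 2 the count was 2. At an unadjusted p under 0.05, limma listed 797 features where 324 would be expected by chance. This count was 353 without Pt(IV) chloride replicate 3, 1273 without Pt(IV) chloride replicate 2, and 1460 with the replicate block. Without cisplatin replicate 2 or 3 it was 471 or 478. For 6255 features (96.6%) the difference had a 95% interval within 1 log2 unit of 0. None of 3111 intergenic features passed limma, with 395 at an unadjusted p under 0.05, and none passed with the replicate block, with 640. The slide position of the arrays followed the compound, with cisplatin in 1 row of the slide and Pt(IV) chloride in another, so row and compound cannot be told apart.

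The 47 measured ribosomal protein genes were slightly higher with cisplatin as a group. Their mean level was 2.54 ± 0.02 (SD, n = 3) with cisplatin and 2.32 ± 0.11 (SD, n = 3) with Pt(IV) chloride, a 1.16-fold difference, and 41 of the 47 were higher with cisplatin. The largest positive differences were those of rpmJ (0.44), rplC (0.43) and rpsT (0.43), while rplM went the other way (-0.59, 95% interval -1.10 to -0.07). No member passed the threshold, either over all genes or adjusted over the list alone. The list passed limma camera with a preset correlation (adjusted p = 1.61e-12) and no longer passed with an estimated correlation (adjusted p = 0.453) or with fry (adjusted p = 0.152). Groupings of the arrays that mix the compounds also gave it small p with the preset correlation. The unadjusted camera p was 4.31e-10 with cisplatin replicates 1 and 3 and Pt(IV) chloride replicate 2 set against the rest. It was 1.34e-13 for the real grouping, and in other mixed groupings it reached 0.734. The exact two-sided permutation test of the list mean over the 6 arrays, which left the pairing by replicate number aside, gave p = 0.1, the smallest it allows.

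Genes of protein quality control and of the tricarboxylic acid cycle had small differences in the same direction that did not pass. Of 7 chaperone and protease genes, 6 were higher with cisplatin, among them tig (0.27), clpS (0.26) and clpX (0.25), and the chaperonin gene groEL differed by -0.01 (95% interval -0.26 to 0.24). All 5 tricarboxylic acid cycle genes were higher with cisplatin, with gltA, which encodes citrate synthase, at 0.29 and the succinate dehydrogenase genes sdhA and sdhB at 0.33 and 0.29. The camera adjusted p was 0.0675 for the first list and 0.0705 for the second, and 0.0484 for each with the replicate block. With an estimated correlation the adjusted p was 0.453 and 0.728, and with fry 0.110 and 0.307. The first list also passed without cisplatin replicate 2 (adjusted p = 0.0290) or Pt(IV) chloride replicate 3 (adjusted p = 0.0233), and the second without Pt(IV) chloride replicate 2 (adjusted p = 0.0468).

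No gene of the DNA damage list passed between cisplatin, known as a DNA cross-linking agent, and Pt(IV) chloride. The recombinase gene recA stood at 3.12 ± 0.28 (SD, n = 3) with cisplatin and 3.38 ± 0.23 (SD, n = 3) with Pt(IV) chloride, a difference of -0.26 whose 95% interval without the block ran from -0.67 to 0.14. It was lower with cisplatin in each of the 3 same-numbered pairs, and its limma adjusted p was 0.511 without and 0.172 with the replicate block. Of the 12 measured members 5 were higher and 7 lower with cisplatin, none passed, and the camera adjusted p was 0.666, with a direction opposite to the list's mean of -0.02. The flagellar and motility list of 20 genes split evenly, with 10 higher and 10 lower (camera adjusted p = 0.666). The 16 features of aminoacyl-tRNA synthetase genes had a mean difference of 0.05 (camera adjusted p = 0.176), and the 5 ammonium and urea genes one of -0.02 (camera adjusted p = 0.998, opposite in direction to the mean).

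Metal resistance loci were measured through lists of locus tags, set from general knowledge of this strain, since the files pair none of these tags with a name or function. The 20 copper and gold loci had a mean difference of -0.10 between cisplatin and Pt(IV) chloride, the 5 zinc, cobalt, nickel and lead efflux loci one of -0.08, and the 8 arsenic loci one of -0.13. The 8 metal uptake loci were at -0.09 and the 10 loci of iron acquisition at -0.04. The camera adjusted p of these lists was 0.176, 0.666, 0.176, 0.584 and 0.880 in that order, and no member passed. Among lists of fewer than 5 genes, the phosphate transporter gene pstA was 1.27-fold higher with cisplatin (log2 difference 0.35, 95% interval 0.17 to 0.53), which passed adjusted over the list alone of 3 genes (limma adjusted p = 0.00796) and not over all genes (limma adjusted p = 0.392). Over the alternative settings the log2 difference of pstA ran from 0.10 to 0.39. The others of these genes were ugpQ (0.06), cysS (-0.08) and atpC (0.13), and pstC (0.01), cysM (-0.07) and rbcL (0.25), whose sign changed under some settings.

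The Au-NP array was set against the 6 platinum arrays as a description of 1 sample with no replicate. It differs in metal, dose and time at once, so no difference can be assigned to any of these, and no test was made. On this array 213 of 6505 gene features lay at least 1 log2 unit above the range of all 6 platinum arrays, and 341 lay as far below it. The same rule applied to each platinum array against the other 5 gave between 0 and 9 features. Those 5 held arrays of the same compound and the array of the same number, whose shared shifts are then not counted. The Au-NP array had no other array of its treatment, so these counts do not measure its noise. Among 3138 intergenic features 114 (3.6%) lay above and 127 (4.0%) below, against 3.3% and 5.2% of gene features. Of the 6505 gene features 2246 lay within the platinum range, so a value outside it by a smaller margin was common.

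Flagellar genes were far lower on the Au-NP array than on every platinum array. All 20 measured flagellar and motility genes lay below the range by at least 1 log2 unit, with a median difference of -3.83, or 14.3-fold. The median stayed at -3.83 with genes that were not well above background set to their bound, and it lay below all 10000 random lists matched on expression, the lowest of which was at -0.61. The hook gene flgE differed by -4.88, the rod gene flgG by -5.05, the stator gene motB by -3.72 and the basal body ring gene fliF by -1.44. The rotor gene fliG, the export gene fliP and the hook cap gene flgD were not well above background on the Au-NP array and were at least 29.4-fold, 35.1-fold and 18.6-fold lower. With normexp background correction, which compresses dim signals, the log2 differences of fliG, fliP and flgD were -2.42, -2.70 and -1.65, those of flgE, flgG, motB and fliF were -2.69, -3.34, -2.30 and -1.04, and the list median was -2.20.

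Part of the DNA damage list was higher on the Au-NP array. The features that the files name dnaE2 (with or without a further digit), after an error-prone DNA polymerase subunit, differed by between 2.55 and 2.79 over 4 features. The recombinase gene recA differed by 1.71, or 3.27-fold, and recX, a modulator of RecA, by 1.20, or 2.30-fold. In contrast ruvA (-0.09), ruvB (-0.45), ruvC (0.23), recO (-0.12, with the sign turned under 2 settings), recR (0.36) and mutL (0.35) lay less than 1 log2 unit from the platinum mean. The median of the 12 members was 0.78, above all 10000 random lists, with the dnaE2 features counted separately. Without the 4 dnaE2 features, a choice made after seeing the data, it was 0.29 over 8 members, at percentile 91.3.

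All 10 loci of the iron acquisition list, a consecutive stretch of locus tags taken to hold siderophore genes, were higher on the Au-NP array than on every platinum array. Their differences ran from 0.43 to 2.81 with a median of 1.91, or 3.76-fold, above all 10000 random lists, and 9 of them lay outside the platinum range by at least 1 log2 unit. The random lists held scattered features, so this rank treats neighbours that may move together as separate. None of the 20 copper and gold loci lay outside the platinum range by 1 log2 unit. Their median difference was 0.13 (percentile 80.5), their values ran from -0.60 to 0.40, and 10 lay within the platinum range. The arsenic loci had a median of -0.23 (percentile 7.6), the zinc, cobalt, nickel and lead loci -0.07 (percentile 37.4, with the sign turned under 1 setting) and the metal uptake loci 0.14 (percentile 72.6), and no member of these lists was outside by 1 log2 unit.

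**Figure D2:**
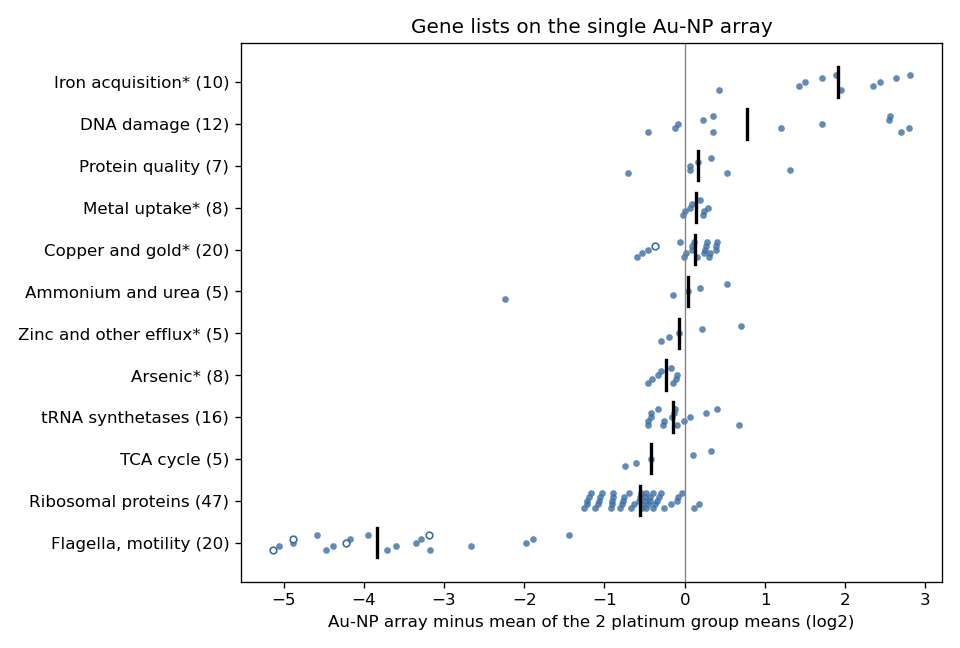
Difference of the single Au-NP array from the mean of the platinum group means (horizontal axis, log2) for every measured member of 12 gene lists (vertical axis, number of members in brackets). Each point is a feature, open points are features not well above background on the Au-NP array drawn at their bound, black bars are list medians and an asterisk marks lists set by locus tag. The flagellar genes well above background lie between -5.05 and -1.44 and the 10 iron acquisition loci between 0.43 and 2.81.

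Ribosomal protein genes were modestly lower on the Au-NP array, with a median difference of -0.56 over 47 genes, below all 10000 random lists. Of these, 41 lay below the platinum range, none by 1 log2 unit, and the farthest were rplW (-1.26), rplD (-1.21), rplB (-1.21) and rplV (-1.19). Protein quality control genes had a median of 0.16 (percentile 74.4), with hslU, the ATPase of a heat-shock protease, at 1.32, clpS at 0.52, groEL at 0.32 and tig at -0.71. The tricarboxylic acid cycle list had a median of -0.42 (percentile 14.04), the tRNA synthetase list -0.15 (percentile 22.0) and the ammonium and urea list 0.05 (percentile 55.2, with the sign turned under 1 setting). Within the last, gltD, a glutamate synthase subunit gene, stood alone at -2.24. The lists of this paragraph hold only features named by symbol, whose median over 329 features was -0.21, against 0.03 for all gene features. In the lists too short for a percentile, pstA was at 0.73, pstC at 0.44, ugpQ at -0.47, cysM at 0.45, cysS at 0.27, atpC at -0.27 and rbcL at -0.97. The platinum arrays themselves ran from 0.16 to 1.64 for rbcL, which varied by replicate number, and the Au-NP array lay 0.22 below that range.

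Beside the flagellar genes named by symbol, several features far from the platinum arrays were known by locus tag alone. What these encode, flagellar or other, was not looked up. Rmet_3749 was 58.0-fold higher on the Au-NP array and Rmet_3868 36.7-fold higher, while Rmet_3735 was 62.7-fold lower and Rmet_3686 41.4-fold lower. With normexp background correction the log2 differences of these 4 features were 5.41, 2.78, -3.48 and -4.51 in that order, against 5.86, 5.20, -5.97 and -5.37. Under the same correction the iron acquisition median was 1.16, and the counts were 146 higher and 217 lower. In the authors' value table the median of the DNA damage list was 0.22, where 9 of its 12 members had a row and the dnaE and dnaE2 features shared a single one.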

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

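The alternatives with intergenic features in the same fit and with both arrays numbered 1 left out were chosen after seeing the data. The count of genes that differed between cisplatin and Pt(IV) chloride was 3, and it stayed at 2 or 3 with normexp, quantile normalization, median centring, the filter on all 6 arrays, the brightest probe, the trended and robust spread and the threshold of 1 log2 unit. It was 1 with the authors' value table, with no filter on dim probes, with outlier-flagged spots kept, at an adjusted p under 0.01, with intergenic features in the same fit and without both arrays numbered 1, and 5 with array weights. With the replicate block, which pairs arrays by number, it was 1, and leaving out each array gave 1 to 2. The feature behind each count of 1 was Rmet_R0051, whose log2 difference lay between 2.04 and 2.13 in the scanner values under every setting, and was 1.60 in the value table, where its row matched the mean with Rmet_R00510 (adjusted p 1.15e-05 to 0.0217 over all settings). Rmet_R00510 and Rmet_5144 stood at the threshold, with adjusted p from 0.0094 to 0.581 and from 0.0145 to 0.581. The log2 difference of Rmet_R00510 lay between 0.98 and 1.13, and that of Rmet_5144 between -1.35 and -0.59, the last with normexp. Settings that leave out arrays or add features test with fewer samples or over more features, and for the others the cause was not tested.

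Of 12 gene lists 1, that of ribosomal proteins, passed camera. The count was 3 with normexp and with the replicate block, where the protein quality and tricarboxylic acid cycle lists joined, 2 with array weights, and 0 with an estimated correlation and with fry. Leaving out each array gave 1 to 2, with 2 without cisplatin replicate 2 or Pt(IV) chloride replicate 2 or 3. The block changed no other list's call.

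On the Au-NP array the counts of 213 higher and 341 lower (554 in all) became 146, 217 and 363 with normexp, all 363 of them among the 554, and 62, 153 and 215 when 2 log2 units outside the range were asked for. All other settings stayed within 1.5 times, and at the threshold of 1 log2 unit lower features made up 57.5% (median centring) to 67.3% (value table) of the total. Leaving out each platinum array gave 215 to 232 higher and 345 to 376 lower. Normexp also moved the median difference of all genes to 0.111 from 0.030, and its added offset compresses differences of dim probes. No paired analysis was possible for the Au-NP array because it has no replicates. Of the 3296 values of named genes on this array under alternatives 284 moved by more than the spread within the platinum groups and none of those outside the range turned direction. A slide block was not run because there was 1 slide. Signals near background limit what can be said of genes low on the Au-NP array, where 26 of the 341 had only a bound.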

Other observations

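The lists, the tests on the features that follow below and the explanations weighed were chosen after the results were seen, except that the test on array brightness and the counts over other splits were set before their results were seen. On the Au-NP array, 17 features of translation and ribosome assembly factors had a median difference of -0.54 (percentile 0.45 among matched random lists). Of these 12 lay below the platinum range, none by 1 log2 unit. A list of 12 transcription features, which holds several features of the RNA polymerase gene rpoB beside elongation and termination factors, had a median of -0.46, and none of its members lay outside the range by 1 log2 unit. The 6 features named putA, after the proline oxidation enzyme, had a median of -0.91. No percentile is given for the transcription and putA lists, in which 6 members are features of a single gene name. The translation and nucleotide lists, and the tRNA synthetase list, also count some genes (infB, carB, ileS and valS) by more than 1 feature, so their percentiles treat these as separate. Genes of amino acid synthesis were at -0.20 (percentile 7.44), nucleotide synthesis at -0.20 (percentile 9.78), protein secretion at -0.16 (percentile 27.8) and cell wall synthesis at 0.17 (percentile 79.6). The added lists hold only features named by symbol, whose median over 329 features was -0.21, against 0.03 for all gene features. The random lists were drawn from all gene features, so a median near -0.21 does not set a list apart from the symbol class. The 3 features named dnaE without the added 2, after the replicative polymerase, had a median of 0.17, against 2.63 for the 4 dnaE2 features. Other gene symbols outside the platinum range by at least 1 log2 unit, beyond those already named, were putA0 (-1.17), putA4 (-1.51), ntpA (1.74), livG (-1.28), the periplasmic disulfide isomerase gene dsbG (1.86), the periplasmic glucan gene mdoG__1 (1.42) and the lipoprotein acyltransferase gene lnt (-2.90). With normexp the differences were -0.05 for putA0, -0.68 for putA4, -0.98 for livG and -1.92 for lnt.

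Features that set the Au-NP array apart sat next to each other by locus tag. Of 478 tags outside the platinum range, 319 (66.7%) had an adjacent tag outside in the same direction, where 1000 shufflings of the directions over the tags gave a median of 37 and at most 66. There were 26 runs of at least 4 consecutive tags, 16 lower and 10 higher, the longest with 13 lower loci (median difference -3.16) and with 12 higher loci (median 2.06). What these loci encode was not looked up, since the files do not name them.

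The platinum arrays held a shared structure by replicate number, whose size was not set against the compound difference on a like measure. In both groups 62 features differed in the same direction by at least 1 log2 unit between the arrays numbered 1 and 2, and none did so in opposite directions. Their median shift was 1.47, or 2.76-fold, and 39 of them lay in 7 runs of at least 3 consecutive tags. Among the named ones rbcL, the large subunit of the carbon dioxide fixing enzyme, stood at 0.21, 1.64 and 1.26 on cisplatin arrays 1, 2 and 3 and at 0.16, 1.45 and 0.74 on Pt(IV) chloride arrays. The phosphoglycerate kinase gene pgk__2 stood at 0.05, 1.53 and 1.09 and at 0.12, 1.43 and 1.05, while ssrA, the transfer-messenger RNA, was lower on the arrays numbered 2. For 58 of the 62 the arrays numbered 3 lay nearer to those numbered 2, and the Au-NP array lay nearer to the arrays numbered 1 for 38 of them.

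This structure may reflect cultures or RNA preparations shared between same-numbered samples, which the labels do not state and which was not tested. Arrays numbered 1 were dimmer than those numbered 2. The 100 genes of nearest level shifted by a median of 0.0238 on the log2 scale. Scaling within each array already removes a brightness difference shared by all genes, so this small shift cannot decide on array brightness. It shows only that the 62 features stood apart from genes of similar level. A slide column effect would put cisplatin replicate 1 and Pt(IV) chloride replicate 2, which shared a column, at 1 level, but over the 62 features they differed along the shift by a median of 1.44, against 0.04 between the arrays numbered 1. The count of such features was 62 with quantile normalization, 63 with median centring and 45 with normexp.

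For the higher level of Rmet_R0051 and Rmet_R00510 with cisplatin, the tables argue against a flaw of single spots. The features have 4 probes at separate places, of which each pair overlaps in sequence, and the medians of the spots around them lay no farther from 0 than -0.0726. The log2 difference of Rmet_R0051 was at least 2.06 with normexp, quantile normalization and median centring of the scanner values. The 75th percentile signals of the platinum arrays lay between 383 and 492. Another scaling could therefore move this bright feature only a little, and the unchanged difference adds no support. What stays open is a slide row or RNA preparation effect, since both followed or may have followed the compound. The Au-NP array, in the row of the Pt(IV) chloride arrays, differed from their mean by 0.288 for Rmet_R0051, so row and treatment cannot be told apart, and a response to cisplatin remains an untested candidate.

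For the low flagellar genes on the Au-NP array, a dim array was weighed with matched random lists, whose lowest median of 10000 was -0.607. Since values were scaled within each array, most genes of the flagellar level stay near 0 whatever the array's brightness. The random lists therefore cannot decide on a dim array. They show only that the flagellar genes stood apart from other genes of their level. Scaling is argued against by the flagellar median of -2.20 at its nearest to 0, with normexp, over the background and scaling alternatives. The metal, the dose, the longer exposure, the growth state at harvest and the culture itself all remain open for this 1 sample.

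Over other splits of the 6 platinum arrays, 10 in all, the real one gave 3 genes and the highest of the others 1, and 1 of the 10 splits, the real one itself, gave as many. For gene lists past camera the real split gave 1 and the highest other 4, and 9 of the 10, the real one included, gave as many. The split with 4 lists set cisplatin replicates 1 and 2 with Pt(IV) chloride replicate 1 against the rest. The 3 splits other than the real one that also part all same-numbered arrays gave 0 genes each by limma and 0 to 1 lists, with 81 to 129 features at an unadjusted p under 0.05. The split of cisplatin replicate 1 with Pt(IV) chloride replicates 1 and 3 gave 1229 such features, more than the 797 of the real one, which points to a structure of the samples. With 10 splits no share under 0.05 can be reached.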
